A study of Mus musculus with 61 samples.

How the data were processed

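RNA of skeletal muscle was sequenced from 61 libraries of 8 inbred mouse strains, named as in the labels AJ, B6, 129, NOD, NZO, Cast, PWK and WSB, and each library was assigned to its strain by its title. All libraries carried the same diet label, 45 percent fat, and no strain was labelled as a control. The labels gave no sex, age or batch, and did not say that the libraries of a strain came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. Each strain held libraries high in Xist, a female transcript, and libraries high in Ddx3y, a male transcript. The spread and SD within a strain can therefore include sex, which the main fit left in the spread. The titles also held a number within the strain and 2 running numbers, with the prefixes ORSAM and GT20, whose meaning was not explained. The series title lists further tissues, which were not analysed here.

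Per the labels' protocols, the authors pulverised frozen tissue, extracted RNA, added an ERCC spike-in mix, selected polyadenylated RNA with oligo-dT beads and built libraries with the KAPA mRNA HyperPrep kit. The aligner, the counting tool, the annotation release and the use of strand in counting are not given in the sources used here. Per the submitters' processing notes, the genome build was GRCm38 and DESeq2 was used, without a version or a role. Whether reads of all strains, including the wild-derived Cast, PWK and WSB, mapped equally well to this build was not tested. The authors deposited expected counts (estimated reads per gene, not scaled) for 19462 genes, of which 80.4% of the values were whole numbers. Every gene in the table had a count of at least 1 in at least 30 libraries, and 0 of its genes were ERCC spike-ins. The authors also deposited variance-stabilised values on a log2 scale for the same genes, from 5.87 to 25.11, with settings that are not given. The deposited annotation gave gene starts and ends in megabases on GRCm38. Of the gene IDs, 19388 were found in GENCODE release M21, all on the same chromosome and 15555 with both ends equal. A symbol stood on more than one ID for 36 symbols, which are printed with the ID, and 23 symbols that a spreadsheet had turned into dates were taken from the variance-stabilised table.

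The design had assumed whole counts. The expected counts were therefore rounded to whole numbers before testing. Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) after filterByExpr, which kept 16682 genes, and TMM normalisation. One fit held all 61 libraries with strain as the single factor and 53 residual degrees of freedom, so that the strains shared one estimate of spread per gene. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and every adjusted p of a gene in the text comes from this test unless another is named. The comparisons were all 8 strains together, each strain against the equally weighted mean of the other 7, and the mean of the 3 wild-derived strains (Cast, PWK, WSB) against that of the 5 classical strains. Fold changes are differences of log2 coefficients, and their standard errors (SE) were taken as the absolute log2 difference divided by the square root of F. Levels are CPM (counts scaled by the TMM-adjusted library size), as mean and SD over the libraries of a strain. The level of the other strains is the mean and SD of their 7 strain means.

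Genes were named by a rule fixed before the data were examined, together with the comparisons, tests, 29 gene lists and a set of alternatives. Eligible genes passed the threshold, had a mean of at least 5 CPM over strain means and carried a symbol other than a predicted, clone or pseudogene name. The text names the 16 eligible genes with the largest F among all strains, the 10 highest and 10 lowest in NZO and in the wild-derived contrast, and the 4 highest and 4 lowest in each other strain. It also names up to 2 members per direction of each list described, and all measured genes of a list of variants known in these strains. A few genes that this rule names are not reported here, and no others took their place. List members past the threshold were counted over all genes tested and, separately, adjusted over the list alone. Lists were also tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation and with fry. Leading with member counts in place of camera, and the choice of which lists to describe in which strain, were decided after the values were seen. Lists of hepatocyte, keratinocyte and lymph node markers were also written after the data were seen.

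Genes that share reads with near-identical copies were searched with BLAST 2.17.0 over GENCODE transcripts (at least 95% identity over at least 200 bases and 50% of the shorter transcript). Of 141 named genes, 44 had such a copy elsewhere and 37 overlapped another gene. For these the counting could have divided the reads, and an antisense partner cannot be told apart without strand, so their values are uncertain. Levels of a gene and of its copies were also summed. Adding a more abundant copy narrows a range by itself, so a narrower range alone does not show that reads were divided.

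The alternatives of that set were DESeq2 size factors, DESeq2 tests (DESeq2 1.42.0), no count filter, a stricter filter of 5 CPM in 7 libraries, the number in the title as a block, the GT20 or ORSAM number or the Xist level as a covariate, 2 surrogate variables (sva 3.50.0), limma on the variance-stabilised values, eligible symbols alone, a change of at least 1 log2 unit, B6 as the comparator, and the wild-derived contrast without each strain. Added after seeing the data were covariates for the sums of hepatocyte, lymphocyte and keratinocyte markers, fits without library B6_5, without the 4 libraries whose hepatocyte marker sum was over 3 times the median, without the 6 libraries whose lymphocyte marker sum was over 3 times the median, and without each library in turn. The scores of the 2 largest principal components were correlated with the marker sums, also after seeing the data. For lymphocyte genes, the settings built on the lymphocyte marker sum condition on the values tested. A call of such a gene that is lost under them is no independent check. Each count was set against 100 labellings of the libraries, the real one and 99 drawn at random, and the wild-derived contrast also against all 56 divisions of the strains into 3 and 5. Technical measures and variance shares were tested with 100000 permutations of the strain labels.

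The tests were tried on simulated data: counts were drawn for the 16682 genes from the real means and library sizes, with 200 genes changed in NZO. For NZO, the test recovered 83.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 12 unchanged genes were called, 6.1% of the calls. Of 20 simulated lists of 20 genes each, camera called 5 of the 5 that were shifted and 0 of the others. The simulated genes were drawn independently of each other, so these error rates need not hold for the real data. There, random labellings gave a median of 72 camera calls in 261 list tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.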

Results

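Skeletal muscle transcripts were measured in 61 libraries from 8 inbred strains, the founders of the Diversity Outbred mouse population, which is bred to map genes behind metabolic traits. All mice were on a high-fat, high-sugar diet, so the comparisons ask how muscle transcript levels differ with strain on this diet. AJ, B6, 129, NZO and WSB had 8 libraries each, and NOD, Cast and PWK had 7 each. NZO is a polygenic obese strain and NOD is prone to autoimmune diabetes. Cast, PWK and WSB descend from wild-caught mice of different subspecies.

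The total estimated count was 17.1 to 65.2 M per library (median 33.7 M), and the median library had 14795 genes with at least 10 counts. Total count, the share of the 20 most abundant genes and the share of mitochondrial-genome genes did not differ detectably among strains (permutation test of strain labels, adjusted p = 0.6, 0.36 and 0.36). Rn18s-rs5, a ribosomal RNA gene, held 6.74% of all counts. In library B6_5 it held 46.3%, against at most 9.76% in the other libraries. No 95% Wilson interval of these shares was wider than 0.05 percentage points, counting error alone. Strain accounted for 45.6% of the variance of log2 CPM between libraries, against at most 20.3% in permuted labels (permutation p = 1e-05, the smallest that 100000 permutations can give). The first 4 principal components held 20.6, 12.5, 9.6 and 7.7% of the variance. Strain accounted for 51.5% of the variance of the first and 52.2% of that of the second. Within strains, their scores had a correlation of 0.97 and 0.90 with the log2 sum of hepatocyte markers, and over all 61 libraries of 0.84 (permutation p = 1e-05) and 0.48 (permutation p = 9e-05). With the sums of hepatocyte, lymphocyte and keratinocyte markers as covariates, 14167 genes differed among strains, against 14256 without them.

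Muscle transcript levels differed among the 8 strains for 14256 of 16682 genes (85.5%), and 6442 of them spanned at least 1 log2 unit between strain means. The largest F belonged to Cwc22, a splicing factor gene on chromosome 2 from 77881159 to 77946375 (GRCm38), in a segment known to vary in copy number between strains. Cwc22 stood at 522 ± 56.3 CPM in WSB (SD, n = 8) and 8.81 ± 0.378 CPM in PWK (SD, n = 7), a range of 5.87 log2 units (F = 587.9, adjusted p = 7.79e-46). Hint3, which encodes a nucleotide-binding hydrolase (chromosome 10, 30608141 to 30618479), was lowest in WSB at 2.10 ± 0.209 CPM (n = 8) and highest in Cast at 19.2 ± 2.41 CPM (n = 7; adjusted p = 1.25e-40). Snph, the gene of syntaphilin, which docks axonal mitochondria (chromosome 2, 151590549 to 151632593), was highest in Cast at 77.58 ± 10.98 CPM (n = 7) and lowest in AJ at 0.837 ± 0.223 CPM (n = 8), a range of 6.47 log2 units.

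Of the other leading genes, Tmem132d (chromosome 5, 127781630 to 128433077) spanned 8.04 log2 units, from 0.00904 ± 0.0157 CPM in Cast to 18.3 ± 5.14 CPM in NOD. Pon2, a paraoxonase gene (chromosome 6, 5264147 to 5298455), was lowest in Cast at 4.74 ± 1.05 CPM and highest in NZO at 46.4 ± 3.11 CPM. Knop1 (chromosome 7, 118842222 to 118856254) spanned 1.45 log2 units between AJ and PWK. As3mt, which encodes the arsenic methyltransferase (chromosome 19, 46707443 to 46741095), reached 97.3 ± 15.5 CPM in Cast against 12.9 ± 1.57 CPM in NOD. Tmem132d, Pon2 and Knop1 overlap genes on the opposite strand, so their counts are uncertain. The other 9 of the 16 genes with the largest F have a near-identical copy elsewhere in the genome, and most lost their range once the counts of the copies were added. The range fell from 3.95 to 0.41 log2 units for Rpl27, from 4.53 to 0.54 for Rpl12, from 6.23 to 0.39 for Rpl17, from 5.42 to 0.51 for Rpl9, from 4.60 to 0.49 for Rpl19 and from 4.35 to 0.25 for Atp5g2, a subunit gene of ATP synthase. It fell from 2.71 to 0.62 for Ncoa4 and from 9.78 to 0.63 for AK157302, while Rsph3a kept 2.94 of 3.69 log2 units. Of the genes named further on, Cidea, Cntnap2, Cox6a2, Dysf, Fam213b, Fbxo31, Gabarapl1, Krt10, Myl3, Phkg1, Ndufb5, Me1, Gadd45a, Ddit3, Fabp3, Gapdh, Gpi1 and Hist2h2aa1 also overlap genes on the opposite strand, and Acadl, Col1a2, Foxo1 and Pik3r1 overlap genes on the same strand. Fabp3, Gapdh, Gpi1, Lyz2, Mx1 and Scd2 have copies whose addition left most of the range, 1.09 of 1.09 log2 units for Fabp3 and 2.65 of 3.71 for Mx1.

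**Figure D1:**
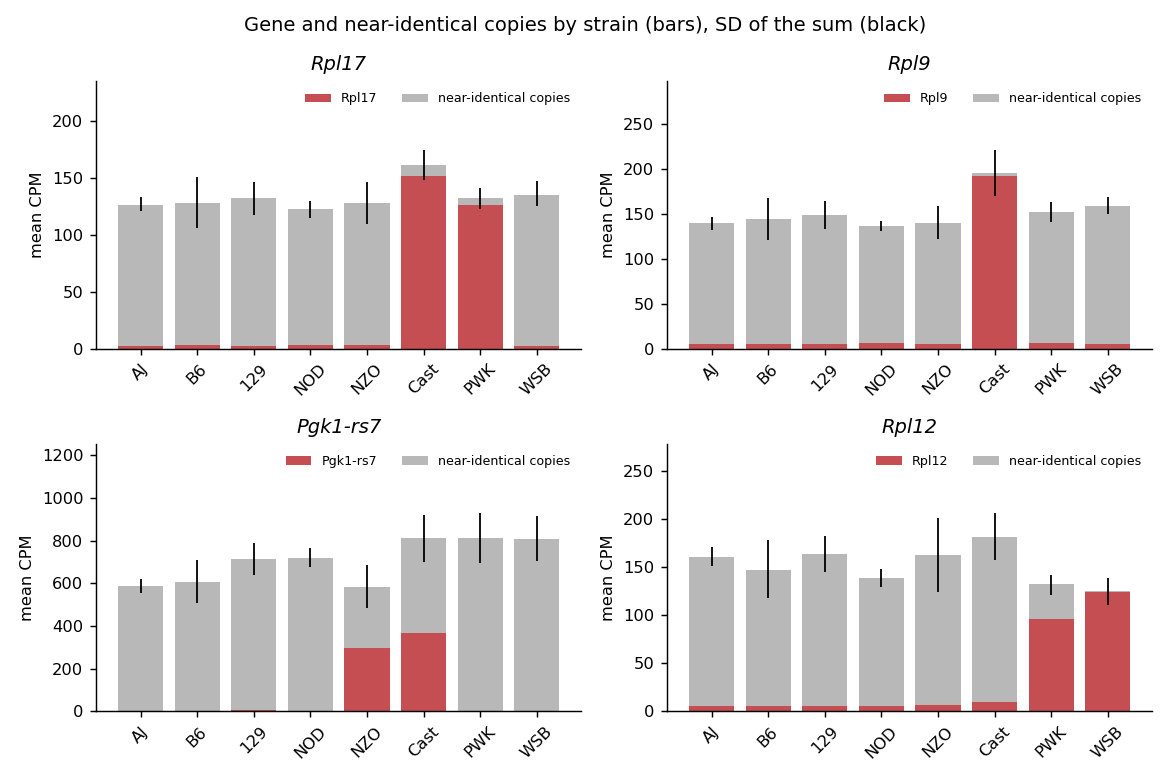
Mean CPM by strain of Rpl17, Rpl9, Pgk1-rs7 and Rpl12 (red) stacked with their near-identical copies (grey), with the SD of the sum as black lines. The share of the gene itself differs between strains, while the range of the sum is 0.39 log2 units for Rpl17 and 0.51 for Rpl9.

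Strain differences reached nearly every fixed gene group, but 85.5% of all genes tested also differed. All measured members differed among strains in the lists of slow fibre (17), fast fibre (17), nuclear-encoded oxidative phosphorylation (71), mitochondrial-genome (13), beta-oxidation (24), protein breakdown (16), unfolded protein response (18), heat shock (21) and interferon-stimulated genes (21). The same held for markers of adipocytes (12), macrophages (11), lymphocytes (11), endothelium (10), fibroblasts and matrix (14), tendon (8), satellite cells (8), smooth muscle and pericytes (10) and erythrocytes (6). The other lists differed in part: PPAR and fasting response 13 of 16, glycolysis 23 of 25, insulin signalling 26 of 27, fatty acid synthesis 17 of 19, cholesterol synthesis 17 of 22, denervation 15 of 16, circadian clock 17 of 18, immediate early genes 10 of 16, antigen presentation 19 of 20 and known strain variants 8 of 9. Of the nerve and Schwann cell markers, 6 of 10 differed. The counts adjusted over the list alone were the same, except 5 for nerve and Schwann cell markers. The PPAR, cholesterol synthesis, immediate early and nerve lists lay below the share of all genes. In single comparisons, the share of all genes called was 31.7% in AJ, 26.2% in B6, 25.6% in 129, 21.6% in NOD and 27.3% in NZO. It was 61.8% in Cast, 41% in PWK, 38.3% in WSB and 58.7% in the wild-derived contrast. These shares hold genes called in either direction, while the list counts that follow are split into higher and lower. A list count in 1 direction is therefore to be set against the genes called in that direction. Their numbers, of the 16682 tested, are given with each comparison. Camera called 60 of 261 list tests, but random labellings of the libraries gave a median of 72, and with an estimated correlation 1 call was left, the known variants in B6. The lowest adjusted p with an estimated correlation among the other list tests was 0.185.

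The known variants gave a check of the strain labels. Nnt, the mitochondrial transhydrogenase gene that is partly deleted in a B6 substrain, was lowest in B6 at 49.5 ± 9.57 CPM (n = 8), against strain means of 108 to 188 CPM elsewhere (adjusted p = 1.21e-19). Dysf, the gene of the membrane repair protein dysferlin, which carries an insertion in AJ, stood at 13.8 ± 1.70 CPM there (n = 8), against 73.9 to 143 CPM in the other strains (adjusted p = 6.65e-34). Glo1, duplicated in AJ, was highest in AJ at 277 ± 11.8 CPM (adjusted p = 6.43e-32). Ifi202b, an interferon-inducible gene, was near 0 in B6 (0.0775 ± 0.107 CPM, n = 8) and Cast (0.0926 ± 0.129 CPM, n = 7) and highest in NZO at 6.92 ± 2.92 CPM (n = 8). Mx1, Cox7a2l and H2-Ea-ps also differed (adjusted p = 4.74e-14, 8.06e-10 and 9.15e-16). Cox7a2l has a near-identical copy, Gm6969, and with it the range over strains went from 0.43 to 0.51 log2 units. Disc1 passed at adjusted p = 0.0235, but not with the marker sums as covariates (0.091) or without the 6 libraries high in lymphocyte markers (0.0576). Hc, the gene of complement component 5, did not pass (adjusted p = 0.408).

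**Figure D2:**
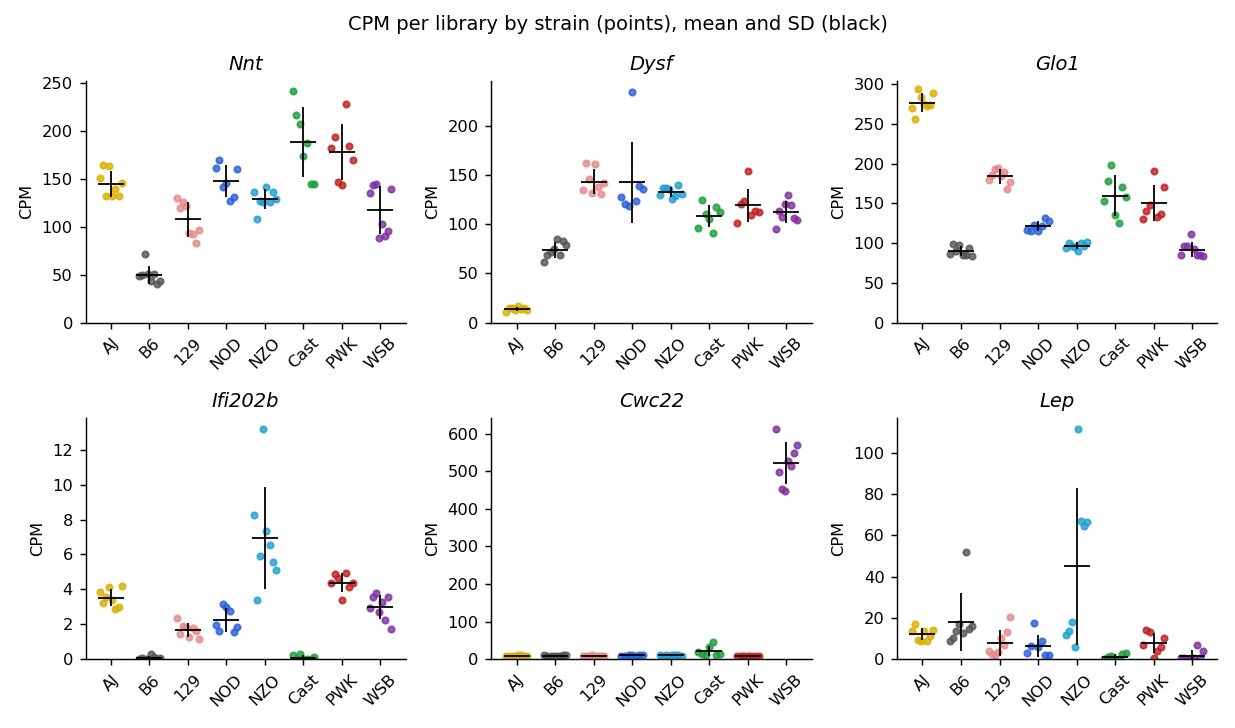
CPM per library (points) by strain for Nnt, Dysf, Glo1, Ifi202b, Cwc22 and Lep on linear axes, with the strain mean and SD in black. Nnt is lowest in B6, Dysf lowest and Glo1 highest in AJ, Cwc22 highest in WSB, and Lep highest and most spread in NZO.

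**Figure D3:**
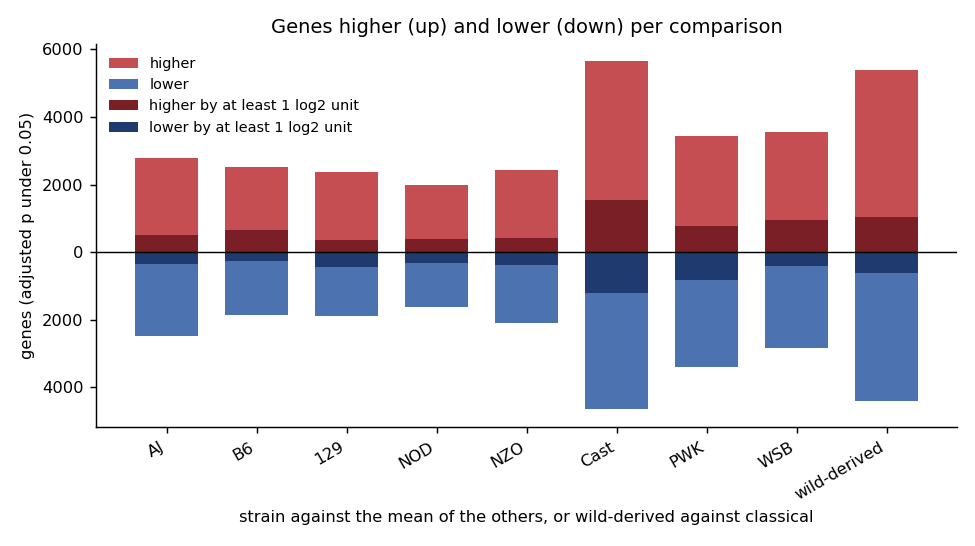
Number of genes higher (red, upward) and lower (blue, downward) at an adjusted p under 0.05 in each strain against the mean of the others, and in wild-derived against classical strains, with changes of at least 1 log2 unit in the darker shades. Cast has the most, 5646 higher and 4661 lower, and NOD the fewest, 1977 higher and 1633 lower.

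In NZO, muscle had more leptin transcript than the mean of the other strains, and higher levels of 11 of 17 slow-fibre genes. Lep, the adipocyte hormone leptin, stood at 44.9 ± 37.9 CPM (SD, n = 8) against 7.9 ± 5.85 CPM over the other 7 strain means, a log2 difference of 2.99 ± 0.37 (SE, adjusted p = 2.42e-09), and 4 of the 8 libraries lay above every library of the other strains. Of the 17 slow oxidative fibre genes, 11 were higher and 0 lower (11 and 0 adjusted over the list alone), among them the slow troponin gene Tnni1 (1.21 ± 0.17, adjusted p = 1.5e-07) and the slow myosin light chain gene Myl3 (1.19 ± 0.14, 2.29e-10). Tendon markers were higher for 7 of 8 (7 over the list alone), including the matrix genes Cilp (1.12 ± 0.13, 2.91e-10) and Kera (0.91 ± 0.21, 0.000504), and endothelial markers for 7 of 10 (7 over the list alone), including Emcn (0.51 ± 0.08, 1.58e-06) and the VEGF receptor gene Kdr (0.45 ± 0.07, 1.59e-06). In all, 4546 genes differed, 2432 higher and 2114 lower, 790 of them by at least 1 log2 unit.

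Of the 21 interferon-stimulated genes, 10 were higher and 0 lower in NZO (10 and 0 adjusted over the list alone; 3 of the 8 tested under the stricter count filter), including Ifi27l2a (1.45 ± 0.27, adjusted p = 2.85e-05) and the antiviral gene Rsad2 (1.18 ± 0.25, 0.000204). Adipocyte markers went both ways, 3 higher and 2 lower of 12 (3 and 2 over the list alone), with a median of 0.14 and a mean of -0.03. Car3 was higher (0.98 ± 0.18, 3.35e-05), and Cfd (-1.58 ± 0.38, 0.00118) and Cidea (-1.23 ± 0.44, 0.0322) were lower. Car3 averaged 1488 CPM over the strain means, against 12.5 CPM for Lep and 6.31 CPM for Cidea. Whether Car3 marks adipocytes in these muscle libraries was not tested. The Cidea call ended without any of NZO_2, NZO_4, NZO_6, NZO_7 and NZO_8 (-1.14 at the weakest, adjusted p up to 0.0663), with the replicate block (-1.13, 0.061), with limma on the variance-stabilised values (-0.65, 0.0589) and with the marker sums as covariates (-1.16, 0.0662). With an estimated correlation, camera's adjusted p was 0.185 for endothelial markers and 0.97 for the other lists named here.

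The further genes with the largest increases in NZO included Lrp2bp (2.98 ± 0.15, adjusted p = 1.02e-23; 20.1 ± 4.74 CPM, n = 8), Kcng4, a potassium channel subunit gene (2.15 ± 0.22, 1.19e-11), Slc15a5 (2.02 ± 0.60, 0.00828), 9930111J21Rik2 (1.71 ± 0.20, 9.94e-10), Gbp6 (ENSMUSG00000104713; 1.71 ± 0.14, 5.59e-15), a guanylate-binding protein gene, and the GTPase gene Rab15 (1.67 ± 0.15, 8.06e-14). Pgk1-rs7 (5.93 ± 0.35), Hba-a1 (3.35 ± 0.27) and Myh6 (2.03 ± 0.14) were also higher, but, like Gbp6 and 9930111J21Rik2, each has a near-identical copy. With the copies added, their range over strains fell from 8.84 to 0.48, from 8.52 to 1.79 and from 4.32 to 1.12 log2 units, while that of 9930111J21Rik2 went from 5.86 to 4.48. The strain means of Myh6 were 2.55 to 57.4 CPM, against 862 to 2000 CPM with its far more abundant copy Myh7 added. The narrower range of Myh6 follows from that addition and does not decide whether its increase is real. The Slc15a5 call ended with limma on the variance-stabilised values (0.93, 0.0903). The lowest genes were Mettl21e, a muscle protein methyltransferase gene (-3.74 ± 0.38, 9.55e-12; 1.56 ± 1.09 CPM, n = 8), and Tceanc2 (-3.47 ± 0.13, 1.94e-29; 0.9 ± 0.205 CPM, n = 8), which lay below every library of the other strains in 8 of 8 libraries. Lrp2bp, Rab15, 9930111J21Rik2, Mettl21e and Tceanc2 overlap genes on the opposite strand. Amd2 (-2.89 ± 0.54), AK157302 (-2.35 ± 0.55), Rpl37rt (-2.32 ± 0.36) and H2-T10 (-2.18 ± 0.25) were lower, all with near-identical copies. Without NZO_6, AK157302 was at -3.46.

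Of the named genes of the epidermis, 3 were lower in NZO: Dmkn (-4.34 ± 1.60, adjusted p = 0.0295), Sbsn (-3.40 ± 0.97, 0.00548) and the keratin gene Krt10 (-3.24 ± 1.10, 0.0271), and 6 of 10 keratinocyte markers were lower and 1 higher (8 and 1 adjusted over the list alone). The log2 sum of the keratinocyte markers did not differ detectably among the 8 strains (permutation test, adjusted p = 0.5). Without NZO_1, Dmkn was at -7.28 and Sbsn at -4.25, and without Cast_8 Krt10 was at -2.58. The Dmkn call ended without any one of the other 7 NZO libraries (adjusted p up to 0.0577), and that of Krt10 without NZO_4 or NZO_8 (up to 0.0508). Both calls also ended with the replicate block (Dmkn -3.83, 0.0993; Krt10 -2.61, 0.104), with surrogate variables (-3.52, 0.0826; -2.30, 0.0993) and with limma on the variance-stabilised values (-1.0, 0.136; -1.0, 0.184).

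Wild-derived strains had higher mean transcript levels than classical strains for 13 of 19 fat synthesis genes, 18 of 21 heat shock and oxidative stress genes and 10 of 12 adipocyte markers. Ucp1, the uncoupling protein of brown fat, stood at 53.4 ± 54.2 CPM over the 3 wild-derived strain means and 0.803 ± 1.43 CPM over the 5 classical ones (log2 difference 7.25 ± 0.61, adjusted p = 2.73e-15), and the lipid droplet gene Cidea at 15.0 ± 9.91 against 1.09 ± 0.336 CPM (3.56 ± 0.28, 1.11e-16). Ucp1 was not high in all wild-derived libraries: 4 of 7 PWK libraries had at most 0.583 CPM, WSB_4 had 0.382 CPM and Cast_3 0.406 CPM, while AJ_1 had 13.5 CPM. Fatty acid and triglyceride synthesis genes were higher for 13 and lower for 3 of 19 (14 and 3 adjusted over the list alone), led by the elongase gene Elovl6 (2.26 ± 0.31, 1.26e-08) and the fatty acid synthase gene Fasn (2.10 ± 0.28, 3.28e-09), with Scd2 (-0.30 ± 0.12, 0.0292) and the malic enzyme gene Me1 (-0.28 ± 0.06, 0.000106) lower. Heat shock and oxidative stress genes were higher for 18 and lower for 2 of 21 (18 and 2 over the list alone), led by the metallothionein genes Mt1 (1.40 ± 0.30, 6.61e-05) and Mt2 (1.11 ± 0.33, 0.00375), with Nqo1 (-0.43 ± 0.05, 9.08e-10) and Txnrd1 (-0.20 ± 0.09, 0.0448) lower. The contrast called 9799 genes, 5382 higher and 4417 lower. Leaving out a strain gave 7720 (without Cast) to 10098 calls (without WSB). The p-values measure the spread between libraries, not between the 3 and 5 strains, so they do not test origin. They also do not separate transcript level from unequal mapping of reads to GRCm38, which was not tested. The other divisions of the strains into 3 and 5 gave 4712 to 8349 calls. The Scd2 call ended without WSB_1, Cast_1 or Cast_6 (adjusted p up to 0.0528), with surrogate variables (-0.26, 0.0602) and without the 4 libraries high in hepatocyte markers (-0.23, 0.132), and that of Txnrd1 without any of 27 libraries (up to 0.09), with DESeq2 size factors (-0.19, 0.0565) and with the GT20 number as a covariate (-0.20, 0.0524). The Txnrd1 call also ended without the 4 libraries high in hepatocyte markers (-0.19, 0.0895) and without the 6 high in lymphocyte markers (-0.15, 0.195), while Txnrd1 was at -0.30 without Cast_5.

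Of the 71 nuclear-encoded oxidative phosphorylation genes, 40 were higher and 2 lower in wild-derived strains (40 and 2 adjusted over the list alone), including Atp5g2 (1.03 ± 0.07, adjusted p = 6.12e-18), and Cox5b (0.43 ± 0.04, 3.22e-13), both uncertain for their copies, against Ndufv1 (-0.14 ± 0.03, 0.000418) and Ndufa12 (-0.10 ± 0.03, 0.00901). Beta-oxidation genes were higher for 15 and lower for 3 of 24 (15 and 5 over the list alone), with Echs1 (0.39 ± 0.05, 7.68e-11) and Acsl1 (0.32 ± 0.05, 6.48e-07) higher and Fabp3 (-0.30 ± 0.08, 0.000778) and Acadm (-0.24 ± 0.05, 1.67e-05) lower. Genes of the unfolded protein and integrated stress response were higher for 13 and lower for 2 of 18 (13 and 2 over the list alone), including Gdf15 (1.10 ± 0.34, 0.0047) and the asparagine synthetase gene Asns (0.72 ± 0.11, 5.32e-08), against Ddit3 (-0.19 ± 0.07, 0.0131) and Dnajc3 (-0.08 ± 0.03, 0.0247). Fibroblast and matrix genes were lower for 8 of 14 (8 over the list alone), including Lum (-0.63 ± 0.11, 6.1e-06) and Col6a1 (-0.57 ± 0.13, 0.000149). The Dnajc3 call ended without Cast_2 or PWK_6 (adjusted p up to 0.0561) and without the 6 libraries high in lymphocyte markers (-0.06, 0.16), and that of Gdf15 with the marker sums as covariates (0.68, 0.0712) or without the 4 libraries high in hepatocyte markers (0.59, 0.151).

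Adipocyte markers were higher for 10, among them Ucp1 and Cidea, and lower for 2 of 12 (10 and 2 adjusted over the list alone). The lower ones were Lep (-2.43 ± 0.37, adjusted p = 1.12e-07) and Car3 (-0.96 ± 0.15, 1.48e-07), which is uncertain as a marker here for its high level. No fit took the adipocyte marker sum as a covariate. Whether the fat synthesis counts of this contrast follow fat tissue in the samples was therefore not tested. All 11 lymphocyte markers were higher (11 over the list alone), with the B cell gene Cd79a at 4.19 ± 0.69 (6.31e-07), as were the immunoglobulin genes Ighg2b (5.25 ± 1.0, 1.71e-05) and Igkc (4.0 ± 0.67, 9.42e-07). The lymphocyte count was 2 with the marker sums as covariates, 3 without the 6 libraries high in these markers, 5 of the 5 tested under the stricter filter and 7 with limma on the variance-stabilised values. The first 2 settings use the sum of these same markers, so a lower count follows from them. The Cd79a call ended with the marker sums as covariates (1.33, 0.0526), and that of Ighg2b with limma on the variance-stabilised values (0.72, 0.0571) and without the 6 libraries (3.18, 0.0807). Leaving out PWK_1 gave 2.87 for Cd79a, WSB_8 gave 4.38 for Ighg2b and Cast_7 gave 3.21 for Igkc. Hepatocyte markers were higher for 7 of 21 (0 over the list alone) and keratinocyte markers for 9 of 10 (9 over the list alone), a number that a random labelling of the libraries also reached. Camera gave, with an estimated correlation, an adjusted p of 0.97 for each list described in this contrast.

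Among the other genes with the largest differences, Kcng4 (-4.69 ± 0.24, adjusted p = 1.77e-24), Lrp2bp (-4.52 ± 0.17, 1.26e-30), the neurexin-family gene Cntnap2 (-4.39 ± 0.17, 5.29e-30), Efcab6 (-2.94 ± 0.18, 3.03e-21) and the class II gene H2-Eb1 (-2.61 ± 0.28, 1.21e-11) were lower in wild-derived strains. Lower genes with near-identical copies or overlapping loci were 9930111J21Rik2 (-3.70 ± 0.21), Gbp6 (ENSMUSG00000079362; -3.34 ± 0.37), Gbp10 (-3.24 ± 0.26), Ly6c1 (-3.19 ± 0.13) and Hist1h4i (-2.67 ± 0.19). Higher genes with near-identical copies were Amd2 (6.35 ± 0.33), AK157302 (6.34 ± 0.48), Rpl17 (3.71 ± 0.12), Rps12 (3.20 ± 0.27) and Rpl12 (3.12 ± 0.08). The mean of Rpl17 was 152 CPM in Cast and 126 CPM in PWK, but 2.25 CPM in WSB. With the copies added, the range over strains fell from 5.70 to 0.81 log2 units for Rps12 and from 8.72 to 1.18 for Ly6c1.

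**Figure D4:**
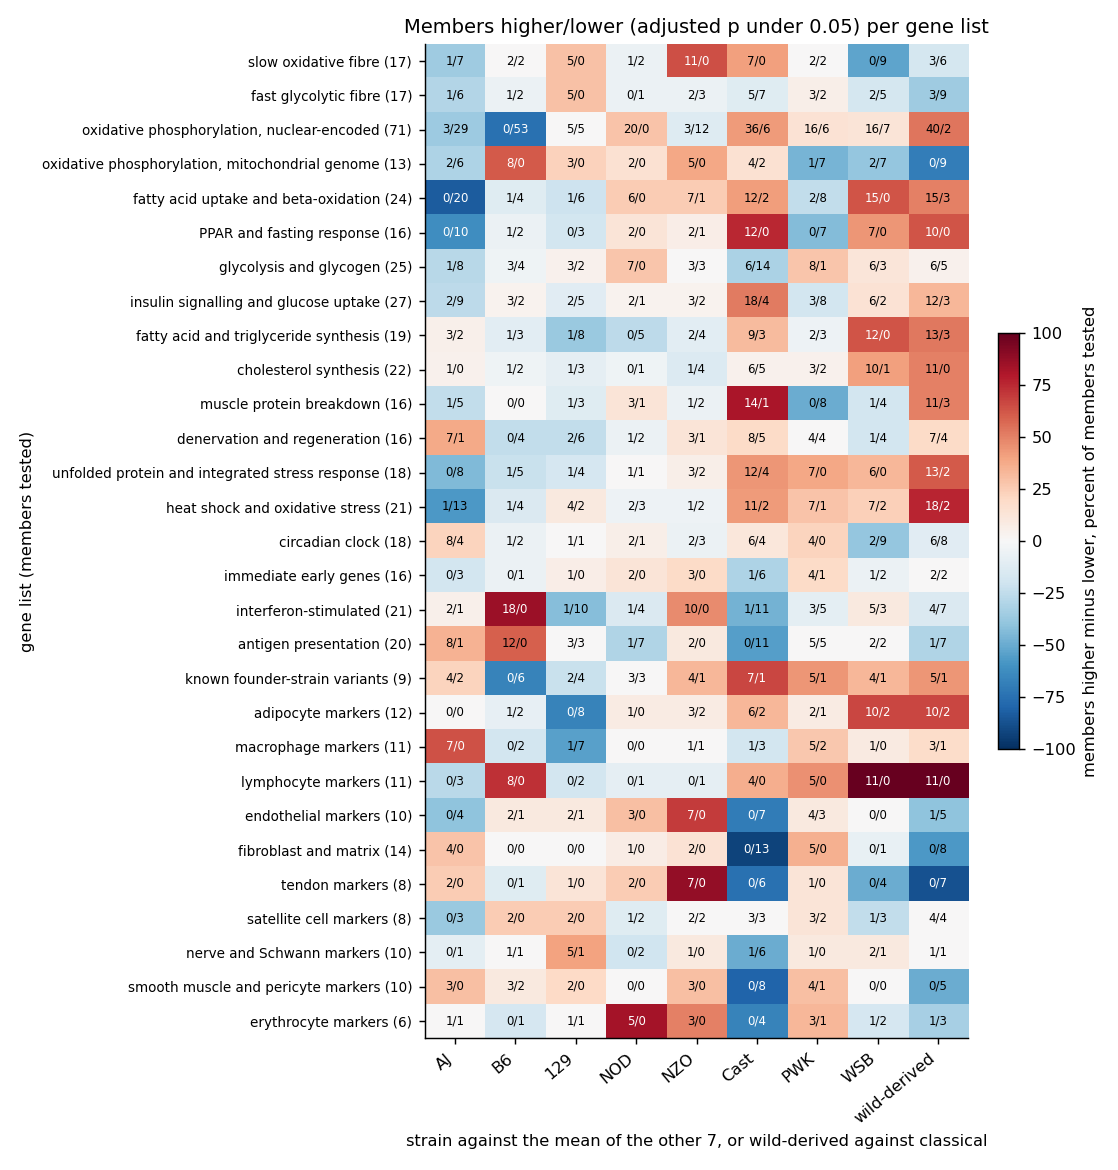
Members higher/lower at an adjusted p under 0.05 for each of the 29 fixed lists (vertical) in each strain and in the wild-derived contrast (horizontal), colored by higher minus lower as percent of members tested. Nuclear-encoded oxidative phosphorylation has 53 of 71 members lower in B6 and 40 higher in wild-derived strains.

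AJ muscle had lower transcript levels of 20 of 24 fatty acid oxidation genes and 13 of 21 heat shock and oxidative stress genes, and higher levels of 7 of 16 genes of denervated or regenerating muscle. Of 24 beta-oxidation genes, 20 were lower and 0 higher (22 and 0 adjusted over the list alone), including the fatty acid binding protein gene Fabp3 (-0.57 ± 0.11, adjusted p = 6.62e-05) and the dehydrogenase gene Acadl (-0.48 ± 0.08, 1.11e-06). PPAR and fasting response genes were lower for 10 of 16 (11 over the list alone), including the thioesterase gene Acot1 (-1.08 ± 0.35, 0.0131), uncertain for its copy Acot2, and the kinase gene Pdk4, which restrains glucose oxidation (-1.0 ± 0.22, 0.000369). Denervation and regeneration genes were higher for 7 and lower for 1 of 16 (7 and 2 over the list alone), with the fetal acetylcholine receptor gene Chrng (3.24 ± 0.37, 2.25e-10) and the perinatal myosin gene Myh8 (1.09 ± 0.15, 5.47e-08) higher and Gadd45a (-0.82 ± 0.20, 0.000879) lower. In all, 5285 genes differed, 2799 higher and 2486 lower. With DESeq2 tests the split was even, 2835 higher and 2835 lower.

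Nuclear-encoded oxidative phosphorylation genes in AJ were lower for 29 and higher for 3 of 71 (34 and 3 adjusted over the list alone), including Cox6a2 (-0.37 ± 0.05, adjusted p = 1.61e-08) and Ndufb5 (-0.36 ± 0.05, 1.89e-07), against Atp5g2 (2.13 ± 0.09), uncertain for its copy, and Ndufc2 (0.18 ± 0.06, 0.0215). Heat shock and oxidative stress genes were lower for 13 and higher for 1 of 21 (15 and 1 over the list alone), with the Hsp70 genes Hspa1b (-2.71 ± 0.55, 9.27e-05) and Hspa1a (-2.04 ± 0.47, 0.000532), which are near-identical copies, lower and Nqo1 (0.24 ± 0.07, 0.00738) higher. Macrophage markers were higher for 7 of 11 (7 over the list alone), including Fcgr1 (1.16 ± 0.30, 0.00172) and Cd68 (0.89 ± 0.19, 0.000175). With the ORSAM number as a covariate, 8 heat shock genes were lower, and the calls of Acot1 (-0.64, 0.198), Gadd45a (-0.51, 0.0511) and Nqo1 (0.18, 0.11) ended. That of Ndufc2 ended without AJ_5 (0.15, 0.08). Camera's adjusted p with an estimated correlation was 0.829 for the beta-oxidation, PPAR and denervation lists and 0.97 for the other lists of AJ.

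The highest named genes in AJ were the class I gene H2-T10 (4.02 ± 0.15, adjusted p = 9.74e-30; 24.7 ± 2.79 CPM, n = 8, above all other libraries in 8 of 8), Gbp6 (ENSMUSG00000079362; 3.0 ± 0.32), Gbp10 (2.96 ± 0.24) and Cntnap2 (2.93 ± 0.14, 9.47e-25). The first 3 have near-identical copies or overlap each other. The lowest were Tmem132d (-4.96 ± 0.55, 1.19e-10), Hba-a1 (-4.39 ± 0.50), the potassium channel gene Kcnf1 (-4.29 ± 0.62, 1.31e-07; 0.291 ± 0.161 CPM, n = 8) and Gvin1 (-3.78 ± 0.55, 1.43e-07). Leaving out AJ_5 gave -5.59 for Tmem132d, and AJ_2 gave -6.12 for Gvin1. Hba-a1 has a near-identical copy, Hba-a2, which was higher in AJ (0.71 ± 0.20, 0.00376), and with it the range of Hba-a1 over strains fell from 8.52 to 1.79 log2 units. With its copies, the range of Gvin1 fell from 7.69 to 2.75 log2 units.

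B6 muscle had lower transcript levels of 53 of 71 respiratory chain genes and higher levels of 18 of 21 interferon-stimulated and 12 of 20 antigen presentation genes. Of the 71 nuclear-encoded oxidative phosphorylation genes, 53 were lower and 0 higher (60 and 3 adjusted over the list alone), including Atp5g2 (-2.28 ± 0.13), uncertain for its copy, and the complex I gene Ndufc2 (-0.40 ± 0.07, adjusted p = 3.89e-06). Interferon-stimulated genes were higher for 18 of 21 (18 over the list alone), including Rsad2 (1.93 ± 0.24, 2.85e-09) and the nucleic acid sensor gene Zbp1 (1.33 ± 0.33, 0.00156). Antigen presentation genes were higher for 12 of 20 (15 over the list alone), including the near-identical class I genes H2-Q7 (2.66 ± 0.28, 2.82e-11) and H2-Q6 (2.25 ± 0.28, 3.25e-09). Whether reads of the class I genes map to GRCm38 equally well in B6 and in the other strains was not tested. Their difference in level is therefore uncertain. In all, 4374 genes differed, 2509 higher and 1865 lower, and 1 of 99 random labellings of the libraries gave more, 4415. With limma on the variance-stabilised values the split was nearly even, 2181 higher and 2108 lower.

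Lymphocyte markers were higher in B6 for 8 of 11 (8 adjusted over the list alone), including Cd79a (3.77 ± 0.72, adjusted p = 4.36e-05), beside a wide spread of the marker sum, 13.1 to 247 CPM over the B6 libraries. The count was 4 of the 5 tested under the stricter filter, 0 with limma on the variance-stabilised values, 5 with the replicate block and 5 with the marker sums as covariates. The interferon count was 11 without the 6 libraries high in lymphocyte markers and 6 of the 8 tested under the stricter filter. Library B6_1 decided several values: without it Zbp1 was at 0.75 (0.117), Cd79a at 2.33, Ighg2b went from 4.99 to 1.05 (0.569), Igkc from 3.16 to 0.45 (0.776) and Ucp1 from -7.43 to -8.34. In mean level Ighg2b was not higher in B6, at 6.28 ± 16.7 CPM (SD, n = 8) against 7.19 ± 18 CPM over the other strain means. It was highest in Cast. Igkc stood at 15 ± 36.5 CPM in B6 against 9.38 ± 16.8 CPM. The log2 differences average log2 coefficients over strains, so they can differ from a ratio of mean CPM. With limma on the variance-stabilised values, Cd79a was at 0.57 (0.215), Ighg2b at 0.49 (0.494) and Igkc at 0.39 (0.652), and with the replicate block Igkc was at 2.22 (0.0683). With the marker sums as covariates Igkc was at 1.45 (0.144). Without the 6 libraries high in lymphocyte markers, the calls of Zbp1 (0.86, 0.0628), Ighg2b (2.21, 0.0659) and Igkc (1.63, 0.0799) ended. The other highest named genes were Gvin1 (4.10 ± 0.29, 1.1e-17), with near-identical copies, and Rn7s1, a signal recognition particle RNA (3.17 ± 0.34), which was at 0.36 (0.3) without B6_5 and at 0.33 (0.296) with DESeq2. Rn7s1 has a near-identical copy, Rn7s2, and with it the range over strains fell from 2.11 to 0.90 log2 units. Also among the lowest were Hba-a1 (-3.96 ± 0.49), with near-identical copies, and Tmem132d (-3.33 ± 0.46, 5.84e-08). With an estimated correlation, camera's adjusted p was 0.829 for the interferon list and 0.97 for the other lists of B6.

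129 muscle had lower transcript levels of 10 of 21 interferon-stimulated genes, 8 of 12 adipocyte markers and 7 of 11 macrophage markers. Of the 21 interferon-stimulated genes, 10 were lower and 1 higher (14 and 1 adjusted over the list alone), with Zbp1 (-1.50 ± 0.44, adjusted p = 0.00741) and the guanylate-binding protein gene Gbp3 (-1.17 ± 0.23, 0.000106) lower and Xaf1 (0.71 ± 0.12, 6.38e-06) higher. Adipocyte markers were lower for 8 of 12 (9 over the list alone), including Cidea (-2.58 ± 0.51, 8.35e-05) and the resistin gene Retn (-2.01 ± 0.45, 0.000462). Macrophage markers were lower for 7 and higher for 1 of 11 (9 and 1 over the list alone), with the lysozyme gene Lyz2 (-0.74 ± 0.23, 0.0134) and Cd68 (-0.65 ± 0.22, 0.0212) among the lower ones. In all, 4268 genes differed, 2374 higher and 1894 lower. With the marker sums as covariates, 7 interferon-stimulated genes and 3 macrophage markers were lower and the calls of Lyz2 (-0.50, 0.173), Cd68 (-0.71, 0.0522) and Zbp1 (-0.83, 0.191) ended. The median lymphocyte marker sum was also lowest in 129, at 15.0 CPM against 23.9 to 167 CPM in the other strains, and 2 of 11 lymphocyte markers were lower (2 over the list alone). Under the stricter filter 4 of 8 interferon-stimulated genes tested were lower. The Cd68 call ended without 129_6, 129_7 or 129_8 (adjusted p up to 0.0608).

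The highest named genes in 129 were Kcng4 (2.70 ± 0.21, adjusted p = 1.54e-15; 44.4 ± 12.2 CPM, n = 8), the cardiac actin gene Actc1 (2.44 ± 0.32, 1.88e-08; 261 ± 243 CPM, n = 8), Cntnap2 (2.37 ± 0.15, 1.32e-19) and Slc15a5 (2.31 ± 0.59, 0.00221). The lowest were Hba-a1 (-4.33 ± 0.50), Gvin1 (-3.95 ± 0.56), both with near-identical copies, and Igkc (-3.64 ± 1.40, 0.0401). Leaving out 129_4 gave -5.09 for Hba-a1, and 129_8 gave -6.62 for Gvin1. The Igkc call ended without any one of PWK_1, 129_2, 129_3, 129_4, 129_6, 129_7, 129_8 and 129_9 (-3.25 at the weakest, adjusted p up to 0.0736), and it was at 0.65 (0.791) with the marker sums as covariates and -2.03 (0.111) without the 6 libraries high in lymphocyte markers. With limma on the variance-stabilised values, Igkc was at -0.83 (0.257) and Slc15a5 at 0.50 (0.412). Camera gave, with an estimated correlation, an adjusted p of 0.97 for each list described in 129.

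NOD muscle had higher transcript levels of 20 of 71 oxidative phosphorylation genes, 7 of 25 glycolysis and glycogen genes and 5 of 6 erythrocyte markers. Of the 71 nuclear-encoded oxidative phosphorylation genes, 20 were higher and 0 lower (29 and 0 adjusted over the list alone; 31 with the marker sums as covariates), including Cox6a2, the muscle form of a cytochrome oxidase subunit (0.74 ± 0.05, adjusted p = 8.46e-20), and Atp5g2 (2.42 ± 0.09), uncertain for its copy. Glycolysis and glycogen genes were higher for 7 of 25 (8 over the list alone), including Gapdh (0.43 ± 0.07, 6.46e-06) and Pgk1 (0.32 ± 0.07, 0.000178), both with near-identical copies. The 7 include Pgk1, whose increase is uncertain: with its copy Pgk1-rs7 added, the mean in NOD was 719 CPM, within the 585 to 813 CPM of the other strains. Erythrocyte markers were higher for 5 of 6 (5 over the list alone), including the globin genes Hba-a1 (4.15 ± 0.27) and Hbb-bt (1.47 ± 0.20, 5.98e-08), which have near-identical copies. In all, 3610 genes differed, 1977 higher and 1633 lower. Tmem132d was highest in NOD (5.92 ± 0.16, 4.14e-37; 18.3 ± 5.14 CPM, n = 7). H2-T10 was also among the highest named genes (3.51 ± 0.16), below Hba-a1. The lowest were AK157302 (-3.64 ± 0.69) and Hist2h2aa1 (-2.96 ± 0.20), with near-identical copies, and Actc1 (-2.98 ± 0.53, 1.6e-05; 9.80 ± 5.67 CPM, n = 7). Leaving out NOD_1 gave -4.38 for AK157302. Camera's adjusted p with an estimated correlation was 0.829 for erythrocyte markers and 0.97 for the other lists.

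Cast muscle had the most differing genes, 10307, with 5646 higher and 4661 lower. Unequal mapping of reads to GRCm38 was not tested and could add to these calls, as it could in PWK and WSB. Genes of muscle protein breakdown were higher for 14 and lower for 1 of 16 (14 and 1 adjusted over the list alone), with the ubiquitin ligase gene Trim63, also known as MuRF1 (2.79 ± 0.23, adjusted p = 5.1e-16), and the autophagy gene Gabarapl1 (2.55 ± 0.17, 4.89e-19) higher and Eda2r (-0.65 ± 0.21, 0.00604) lower. Insulin signalling genes were higher for 18 and lower for 4 of 27 (18 and 4 over the list alone), with the transcription factor gene Foxo1 (2.64 ± 0.19, 8.42e-18) and Pik3r1 (1.46 ± 0.18, 6.4e-10) higher and the adaptor genes Grb14 (-1.18 ± 0.18, 5.88e-08) and Grb10 (-0.33 ± 0.15, 0.0483) lower. Glycolysis and glycogen genes were lower for 14 and higher for 6 of 25 (14 and 6 over the list alone), with Phkg1 (-1.51 ± 0.12, 6.21e-17) and Pgam2 (-1.21 ± 0.14, 1.26e-10) lower and Gpi1 (0.52 ± 0.07, 1.3e-08) and Gbe1 (0.47 ± 0.11, 0.000197) higher. PPAR and fasting response genes were higher for 12 of 16 (13 over the list alone), including the lipase gene Pnpla2 (1.76 ± 0.10, 1.09e-21). Without Cast_5, Pik3r1 was at 0.79, and the Grb10 call ended without any of 34 libraries (-0.21, 0.211 without Cast_6), and with DESeq2 size factors (-0.32, 0.0536), the GT20 number (-0.33, 0.0502) or the ORSAM number (-0.29, 0.0743) as a covariate, or the marker sums (-0.20, 0.206). Eda2r was at -0.54 (0.0527) without the 4 libraries high in hepatocyte markers. Hepatocyte markers were higher in Cast for 10 of 21 (0 over the list alone).

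Fibroblast and matrix genes were lower in Cast for 13 of 14 (13 adjusted over the list alone), including the collagen genes Col6a1 (-1.69 ± 0.22, adjusted p = 2.2e-09) and Col1a2 (-1.56 ± 0.27, 1.14e-06). Antigen presentation genes were lower for 11 of 20 (11 over the list alone), including the class II genes H2-DMb1 (-1.56 ± 0.44, 0.00202) and H2-Ab1 (-1.54 ± 0.48, 0.00455), at -2.45 and -2.30 without Cast_7. H2-DMb1 has a near-identical copy, H2-DMb2, and with it the range over strains went from 2.75 to 2.23 log2 units. The lowest named genes were Fam213b (-7.01 ± 0.29, 1.59e-28; 0.363 ± 0.401 CPM, n = 7), Efcab6 (-6.97 ± 0.39, 1.12e-22), Tmem132d (-6.06 ± 0.49, 3.1e-16) and Retnla, a resistin-like gene (-5.80 ± 0.38, 7.77e-20; 0.279 ± 0.207 CPM, n = 7). Fam213b, Efcab6 and Retnla lay below every library of the other strains in 7 of 7 libraries. The highest were Ighg2b (8.31 ± 0.79, 1.26e-13; 6.25 without Cast_7) and AK157302 (7.26 ± 0.23) and Pgk1-rs7 (6.28 ± 0.36), which have near-identical copies. With an estimated correlation, camera's adjusted p was 0.97 for each list described in Cast.

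PWK muscle had lower transcript levels of 8 of 16 protein breakdown genes and 7 of 16 PPAR and fasting response genes. Muscle protein breakdown genes were lower for 8 of 16 and higher for 0 (9 and 0 adjusted over the list alone), including the F-box gene Fbxo31 (-1.28 ± 0.16, adjusted p = 1.62e-09) and Trim63 (-1.06 ± 0.31, 0.00428). PPAR and fasting response genes were lower for 7 of 16 (7 over the list alone), including the near-identical thioesterase genes Acot1 (-1.86 ± 0.40, 0.000119) and Acot2 (-1.22 ± 0.19, 3.92e-07). Mitochondrial-genome genes were lower for 7 and higher for 1 of 13 (8 and 1 over the list alone), with mt-Co2 (-5.40 ± 0.33) and mt-Nd4l (-5.37 ± 0.13) lower and mt-Nd3 (0.34 ± 0.08, 0.00069) higher. With their nuclear copies added, the ranges of mt-Co2 and mt-Nd4l over strains fell from 6.82 to 0.40 and from 5.64 to 0.49 log2 units, and that of mt-Nd3, which also has a copy, from 1.09 to 1.0. In all, 6834 genes differed, 3442 higher and 3392 lower. The split turned with DESeq2 tests (3426 higher, 3559 lower) and with limma on the variance-stabilised values (3253 higher, 3511 lower). The lowest named genes were the interferon gene Ifi27l2a (-8.07 ± 0.63, 1.88e-16) and Cntnap2 (-7.75 ± 0.37, 9.88e-26), both below every other library in 7 of 7, Slc15a5 (-7.32 ± 1.40, 3.03e-05) and Gbp6 (ENSMUSG00000079362; -6.15 ± 0.75), whose call ended without the 4 libraries high in hepatocyte markers (-5.05, adjusted p = 1). The highest were Tmem132d (5.36 ± 0.16, 4.34e-35; 13.1 ± 2.21 CPM, n = 7) and AK157302 (8.84 ± 0.22) and Amd2 (5.40 ± 0.33), which have near-identical copies. Camera gave, with an estimated correlation, an adjusted p of 0.97 for each list described in PWK.

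WSB muscle had higher transcript levels of 12 of 19 fat synthesis genes, 15 of 24 fat oxidation genes and 10 of 12 adipocyte markers, and lower levels of 9 of 17 slow-fibre genes. Ucp1 stood at 114 ± 124 CPM (SD, n = 8) against 7.16 ± 13.4 CPM over the other strain means (7.17 ± 0.57, adjusted p = 6.24e-16), but at 0.382 CPM in WSB_4. It reached 360 CPM in WSB_9. No fit took the adipocyte marker sum as a covariate. Whether the fat synthesis and oxidation counts of WSB follow fat tissue in the samples was therefore not tested. Fatty acid and triglyceride synthesis genes were higher for 12 of 19 and lower for 0 (12 and 0 adjusted over the list alone), including Fasn (3.03 ± 0.32, 2.24e-11) and Elovl6 (2.75 ± 0.37, 1.38e-08). Beta-oxidation genes were higher for 15 of 24 (15 over the list alone), including Acaa2 (0.44 ± 0.07, 1.93e-07) and the carnitine carrier gene Slc25a20 (0.44 ± 0.05, 1.08e-09). Adipocyte markers were higher for 10 and lower for 2 of 12 (10 and 2 over the list alone; 6 higher without the 6 libraries high in lymphocyte markers), with Cidea (3.69 ± 0.30, 2.16e-15) higher and Lep (-2.39 ± 0.57, 0.000558; -3.28 without WSB_7) and Car3 (-1.05 ± 0.22, 0.000103) lower. Car3 is uncertain as an adipocyte marker here for its high level. Slow oxidative fibre genes were lower for 9 of 17 (11 lower and 1 higher over the list alone), including Ankrd2 (-1.13 ± 0.29, 0.00156) and Myl3 (-1.01 ± 0.16, 9.47e-07). In all, 6391 genes differed, 3562 higher and 2829 lower, and 3971 differed without the 6 libraries high in lymphocyte markers, 4 of them WSB. The Ankrd2 call ended without the 6 libraries high in lymphocyte markers (-0.94, 0.0766).

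All 11 lymphocyte markers were higher in WSB (11 adjusted over the list alone), including Cd79a (4.02 ± 0.71, adjusted p = 6.34e-06) and the T cell gene Cd8a (3.96 ± 0.71, 8.47e-06). Of the 6 libraries high in these markers 4 were WSB, and without the 6 no member was higher (count 0), with Cd79a at -1.37 (0.511) and Cd8a at -4.74 (0.153). With the marker sums as covariates the count was also 0, with Cd79a at 0.89 (0.308) and Cd8a at 0.28 (0.857), and under the stricter filter it was 5 of the 5 tested. The covariates include the sum of these same markers, and the 6 libraries were chosen by it. A loss of these calls follows from both settings and is no independent check. The other highest named genes were Cwc22 (5.61 ± 0.09, 8.82e-50), above every other library in 8 of 8, and Tmem132d (4.73 ± 0.16, 5.57e-32). The lowest were Ly6c1 (-8.82 ± 0.28), with near-identical copies, Lrp2bp (-3.49 ± 0.26, 3.68e-17), H2-Eb1 (-3.19 ± 0.46, 1.09e-07) and Hint3 (-3.09 ± 0.06, 4.09e-44), below every other library in 8 of 8. Camera's adjusted p with an estimated correlation was 0.909 for fatty acid synthesis and 0.97 for the other lists of WSB.

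**Figure D5:**
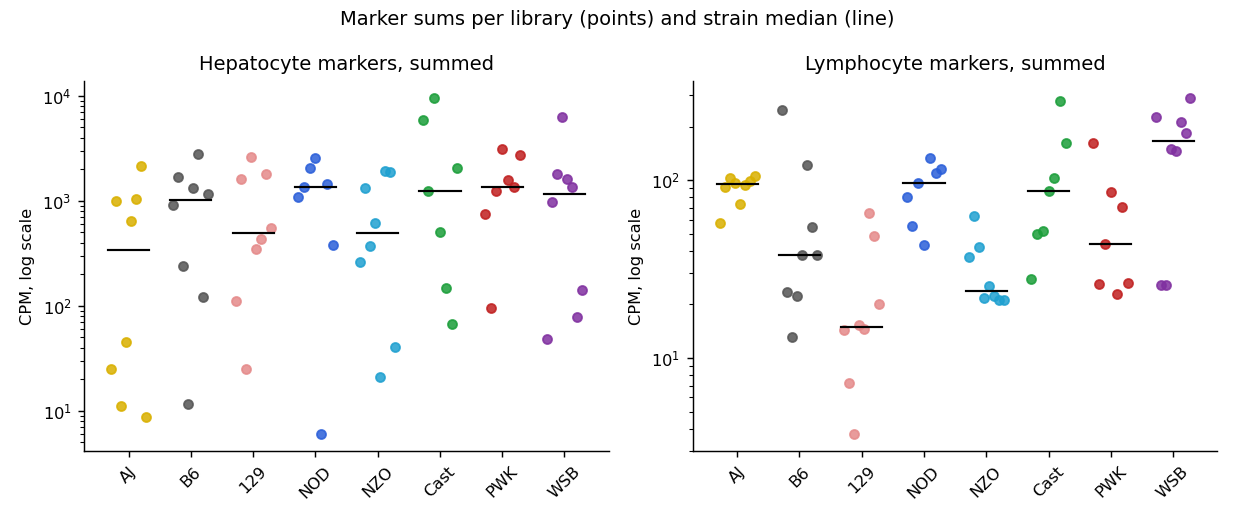
Sums of hepatocyte (left) and lymphocyte (right) marker transcripts per library in CPM, on log axes, by strain, with strain medians as lines. The hepatocyte sum runs from 5.95 to 9560 CPM, and the lymphocyte sum has its highest strain median in WSB, 167 CPM.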

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

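For the weighings in this part, the prediction for blood was written before its result was seen, and the other predictions were written after the result was seen. A library was singled out where its gap to the nearest other library of its strain was large against the strain's whole range, by Dixon's 95% criterion. This met 32 of 181 strain and measure groups (17.7%), in 20 libraries, where chance picks about 1 in 20 groups of normally distributed values. The values were not transformed and need not be normal, so this share cannot be read as an excess over chance.

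Among the technical measures, NZO_2 had 65.2 M counts against 19.7 to 38.9 M in the other NZO libraries, and NZO_1 had 15.6% of counts in mitochondrial-genome genes against 9.24 to 12.1%. In B6_5 the 20 most abundant genes held 75.3% of counts against 36.4 to 40.7% in the other B6 libraries, and Rn18s-rs5 held 46.3% against 4.14 to 9.11%. Rn7s1 stood at 845 CPM in B6_5 against 7.96 to 24.2 CPM. In Cast_7, Rn18s-rs5 held 2.53% against 5.64 to 8.0%.

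Immune genes stood out in several libraries. B6_1 had 47.7 CPM of Ighg2b (at most 1.94 CPM in the other B6 libraries), 105 CPM of Igkc (at most 13.9), 2.03 CPM of Mx1 (at most 0.866) and 0.0565 CPM of Ucp1 (at most 0.0213). Cast_7 had 267 CPM of Ighg2b (at most 68.8 in the other Cast libraries). Mx1 reached 3.89 CPM in NZO_8 (at most 2.34) and 4.21 CPM in PWK_1 (at most 1.48).

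Epidermal and heart-type genes stood out in NZO_1, with 1.57 CPM of Dmkn (at most 0.0976 in the other NZO libraries), 2.14 CPM of Sbsn (at most 0.643), 4.37 CPM of Krt10 (at most 1.2) and 130 CPM of Myh6 (at most 73.3). Genes with known variants stood out in WSB_5 (Hc, which liver expresses, 36.6 CPM, at most 8.58 elsewhere in WSB, in the WSB library with the highest hepatocyte marker sum, 6340 CPM, and Glo1 111 CPM, at most 96.2), in B6_3 (Nnt 71.1 CPM, at most 50.6), in NOD_4 (Dysf 234 CPM, at most 139) and in PWK_4 (Dysf 153 CPM, at most 123). Other single libraries were AJ_3 for Cntnap2 (27.6 CPM), AJ_5 for Kcnf1 (0.654 CPM), AJ_2 for Gvin1 (1.44 CPM), 129_8 for Gvin1 (1.37 CPM), 129_4 for Hba-a1 (2.18 CPM), NZO_3 for Tceanc2 (1.34 CPM), Cast_6 for Snph (100 CPM) and NZO_8 for Pgk1-rs7 (462 CPM). AK157302 stood at 0.175 CPM in NOD_1 and Rpl37rt at 3.29 CPM in NZO_6.

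Lymphocyte transcripts were high in WSB, with a median marker sum of 167 CPM, and differed among strains (permutation test, adjusted p = 3e-05), and B6_1 reached 247 CPM. Within strains, blood left in the tissue did not account for the spread of the lymphocyte sum. There the log2 erythrocyte sum had a slope of -0.04 ± 0.07 on the log2 lymphocyte sum (SE, 95% interval -0.18 to 0.09). A slope within strains cannot decide the difference between strains. Whether some samples held a piece of lymph node could not be told: the sum of the chemokine genes Ccl21a, Ccl19 and Cxcl13 had a slope of 0.47 ± 0.10 (95% interval 0.27 to 0.68), against at least 0.5 expected under this explanation and under 0.25 without it. Taken singly, the slopes were 0.54 for Ccl21a, 0.98 for Ccl19 and 0.58 for Cxcl13, without intervals. In the 6 libraries high in lymphocyte markers, the chemokine sum was 15.2 CPM (WSB_7) to 68 CPM (B6_1). It was also 37.8 CPM in NZO_8, whose lymphocyte sum was 21.8 CPM. A first choice of 6 markers, with a slope of 0.58 ± 0.12, was set aside after its value was seen, because it held Ltb, Cr2 and Cxcr5, which lymphocytes express. Strain could not be excluded, with 6 of 8 WSB libraries above the median of the other strains' libraries.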

How the results depend on the processing

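Most results kept their direction and their side of the threshold. Of 3236 values of 217 named gene results under the alternatives, 3181 did, 52 lost the call and 3 changed sign. The gene count over all strains was 9422 under the stricter filter, which tested fewer genes. A change of at least 1 log2 unit left 6442 genes over all strains, 873 in AJ, 911 in B6, 813 in 129, 733 in NOD, 790 in NZO, 2748 in Cast, 1626 in PWK and 1338 in WSB, by construction. Against B6 alone, AJ had 3118 and NZO 3020 genes. Without the 6 libraries high in lymphocyte markers, 4 of them WSB, WSB had 3971. Camera called 60 list tests, 1 with an estimated correlation, and fry called 104; the cause was not tested.

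With the marker sums as covariates, Igkc in 129 was at 0.65 (adjusted p = 0.791). Without the 6 libraries high in lymphocyte markers, Cd79a in WSB was at -1.37 (0.511) and Cd8a in WSB at -4.74 (0.153). These settings were chosen after seeing the data. They adjust for the lymphocyte marker sum or leave out libraries chosen by it. Shifts of lymphocyte genes can therefore follow from the settings alone, and the cause was not tested.

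Leaving out each library in turn, a setting also chosen after seeing the data, gave 14079 to 14407 genes over all strains, 4687 to 5518 in AJ, 3708 to 4580 in B6, 3657 to 4475 in 129, 2960 to 3823 in NOD, 4098 to 4771 in NZO, 9532 to 10517 in Cast, 6284 to 7054 in PWK, 5648 to 6611 in WSB and 9457 to 10015 in the wild-derived contrast.

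With the number in the title as a replicate block, the counts were 13992 over all strains, 5403 in AJ, 4227 in B6, 4264 in 129, 3575 in NOD, 4596 in NZO, 10215 in Cast, 6658 in PWK, 6459 in WSB and 9404 in the wild-derived contrast, with 62 list tests called. The pairing of numbers was not borne out: the 186 pairs of libraries with the same number had a median correlation of 0.011, against 0 for the 1441 other pairs. In most strains the low numbers were high in Xist and the high numbers in Ddx3y, so the block also takes up part of that difference. Depth limits what can be said of genes near the filter: the smallest library held 17.1 M counts, and B6_5 had 46.3% of its counts in Rn18s-rs5. The effect of depth on these genes was not tested.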

Other observations

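Clock genes were counted in AJ and WSB, a pair of strains chosen after the values were seen. Of 18 circadian clock genes, 8 were higher and 4 lower in AJ (9 and 4 adjusted over the list alone), and 2 were higher and 9 lower in WSB (3 and 10 over the list alone). Dbp, a clock output gene, was at 1.91 ± 0.36 in AJ (adjusted p = 2.27e-05) and -1.43 ± 0.47 in WSB (0.0127), and the repressor gene Nr1d1 at 0.78 ± 0.13 (2.81e-06) and -0.84 ± 0.15 (5.96e-06). Nfil3, which acts against Dbp, was at -1.08 ± 0.23 (0.000214) in AJ and 1.13 ± 0.19 (3.55e-06) in WSB. Without WSB_9, Dbp in WSB was at -2.09. Camera's adjusted p with an estimated correlation was 0.97 for this list in AJ and in WSB. No random labelling gave over 2 higher in AJ or over 1 lower in WSB. Random labels remove the strain differences of all genes, so this does not set clock genes apart. The 2 strains were not tested against each other, and each is part of the mean that the other was compared with. The labels give no time of collection.

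In the relabelling tests, whose predictions were written after the results were seen, the real labels gave more calls than all 99 random ones in all comparisons of genes but that of B6. The rank of the real count among 100 was 1 for all strains (14256, highest other 1874), 1 for AJ (5285 against 1391), 1 for 129 (4268 against 342), 1 for NOD (3610 against 2357), 1 for NZO (4546 against 1029), 1 for Cast (10307 against 3385), 1 for PWK (6834 against 1605), 1 for WSB (6391 against 1361) and 1 for the wild-derived contrast (9799 against 737). For B6 it was 2 (4374 against 4415). Among the 56 divisions of the strains into 3 and 5, the wild-derived division ranked 1 (9799 against 8349). Unequal mapping of the wild-derived strains to GRCm38, which was not tested, could also give this rank. Of 100 labellings, 82 gave as many camera calls of lists as the 60 of the real one, with a highest of 91. For 43 counts of the fixed lists in the report, the larger direction was set against the relabellings, and 41 were above every one. The other 2 were protein breakdown in Cast, with 14 members higher and as many in another labelling, and lymphocyte markers in B6, with 8 against 10. Among the 41, insulin signalling in Cast had 18 against 15, and lymphocyte markers in the wild-derived contrast had 11 against 10. Random labels remove the strain differences of all genes, so this comparison does not set the lists apart from other genes. Of the lists written after the data were seen, the keratinocyte count in the wild-derived contrast, 9, was reached by another labelling.

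Of the tests of the next 2 patterns, the prediction for a common pool of liver libraries was written before its result was seen, and all others after. Muscle libraries held hepatocyte transcripts, whose marker sum ran from 5.95 to 9560 CPM and moved as one mixture, with a median slope of 0.94 of the other markers on Alb within strains, while strain held 10.9% of the variance of the sum. The sum fell with the GT20 number (r = -0.53, permutation p = 1e-05; -0.55 within strains). Xist is a female and Ddx3y a male transcript, and over the 30 libraries with Ddx3y at 66.8 to 200 CPM, Xist (0.0362 to 30.9 CPM) moved with Alb (r = 0.81, permutation p = 1e-05; 0.79 within strains), and over the other 31, Ddx3y (0 to 2.77 CPM) moved with Alb (r = 0.83, permutation p = 1e-05; 0.86 within strains), which argues against liver RNA of the same animal (lower r 0.81). The reads could come from a pool of liver libraries of both sexes, but 0 of 21 markers differed among strains in their share, which a common pool and strain-specific liver RNA without such differences would both give.

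Ribosomal protein genes differed among strains for 74 of 79 tested, 18 of them with a range of at least 1 log2 unit, of which 16 have a near-identical copy. With the copies added, the median range of the 16 fell from 2.09 to 0.45 log2 units (median ratio 0.16), and 0 kept a range of at least 1. Reads divided between near-identical copies could account for these 16. A strain difference of at least 1 log2 unit in the summed level was not seen. Adding a more abundant copy also narrows a range by itself, so the ratio does not show divided reads for each gene. Rpl10 had strain means of 12.2 to 25.1 CPM, against 134 to 177 CPM with its copies. For Rpl17 the copies were low where the gene was high, 152 CPM beside 9.27 CPM in Cast, against 2.16 CPM beside 124 CPM in AJ. For Rpl3 and Rps4l, which have no such copy, no explanation was tested.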
